A study of Mus musculus with 13 samples.

How the data were processed

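Single-cell RNA was measured in dissociated eye tissue of wild-type (WT) mice and of mice from 2 models of retinitis pigmentosa, an inherited disease in which rods and later cones degenerate. The rd10 mice carry a mutation of Pde6b, which encodes a subunit of the rod phosphodiesterase, and the RHO-P347S mice carry a rhodopsin altered at its end, here called P347S. The labels name the tissue as optic cup, the study text speaks of retinas and the protocol of eye samples, so cells from outside the retina may belong to the samples, and shares are of all cells of a library. Tissue was taken at 4 ages in days after birth: WT at P10, P18, P30 and P60, rd10 at P10, P18 and P30, and P347S at P10, P30 and P60. The 13 libraries formed 10 groups, of which P347S at P10, WT at P30 and WT at P60 held 2 libraries each and the other 7 held 1. Per the labels, tissue was dissociated with papain, libraries were made with a droplet kit that reads the 3′ end of transcripts and marks each molecule, and all libraries shared batch 1. The samples were called biological replicates in the labels, but no animals were named, so p-values measured only the spread between these samples, which may be technical.

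The deposited values were whole-number counts of unique molecular identifiers (UMIs) per gene and cell barcode, 1 matrix per library, and per the submitters' processing notes the authors made them with Cell Ranger 7.0.0 and the mouse build mm10. The annotation, the barcode filter, the counting of intronic reads and the use of strand were not given in the sources used here. Each matrix listed 32285 genes, and between 17345 and 48714 barcodes remained per library, 369958 in all. Total UMIs per library lay between 56361495 and 113007156. Gene coordinates came from the GENCODE annotation of the same build, GRCm38, which holds 55450 genes. Whether reads of the altered rhodopsin count towards mouse Rho was not tested.

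Barcodes with at least 300 genes were kept, which left 369557 cells. Doublets were scored per library by simulated neighbours. The automatic thresholds failed, so cells scoring above 0.25 were removed, a value chosen after seeing the data, which marked 35268 cells (7.59 to 11.44% per library) and left 334289. From each library 4000 cells were clustered on 2000 variable genes and 40 principal components with 20 neighbours and the Leiden method at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, seed 1), and the remaining cells took the cluster of their 15 nearest neighbours. A cluster was named for 1 of 20 marker classes where at least 3 markers stood above a log2 fold of 1 against the other clusters at 20 CPM or more (counts scaled to 1000000 UMIs), with a margin of 0.3 to the next class. A cluster also stayed unnamed where its top 10 genes held more markers of another class than of its own. The same held where its UMI count was under 0.333 of the library median and those genes held no marker of its class. These scoring limits were set after seeing the data, and a difference from other work may come from these rebuilt names. Of 44 clusters, 33 were named and 11 stayed unnamed. The unnamed clusters held 73255 cells, 21.9% of the total, and their share per library stands beside the cell shares in the report. Names mean resemblance to the marker set, so "rods" means rod-like cells. By the naming rule no tested class held a cluster with more markers of another class among its top 10 genes than of its own. That outcome was fixed by the naming and does not check the names.

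UMI counts were summed per library and class for rods, cones, Müller glia, bipolar cells and microglia, with at least 20 cells needed per library. The marker class called microglia here covers microglia or macrophages. Cells were not used as replicates. The sums were tested with edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr, a quasi-likelihood F test on group means over all 13 libraries, and Benjamini-Hochberg adjustment at 0.05. The spread came from the 3 groups of 2 libraries, which leaves 3 residual degrees of freedom. A lone library was assumed to vary like the other groups. The prior degrees of freedom were 8.02 in rods, 8.63 in cones, 4.12 in Müller glia, 4.56 in bipolar cells and 5.76 in microglia. Values after "±" are standard errors of a log2 fold change unless marked as an SD, and adjusted p-values come from this test unless another is named. These standard errors were derived from the test, as the size of the log2 fold change divided by the square root of its F value. A mean over ages is the average of the contrasts at the ages that both genotypes shared. The CPM printed beside it are averages of the group levels over those ages, so their ratio can differ from the log2 fold change. Samples were mapped to groups, and tests, gene lists, markers, the rule for named genes and the alternatives were fixed before the data were examined. That rule took Pde6b and Rho in every library, then per comparison the 6 largest rises and 6 largest falls among genes past the threshold with a mean of at least 20 CPM, then up to 4 members of each relevant gene list by adjusted p. The ranked part left out Xist, Tsix and Y-linked genes, mitochondrial, ribosomal protein, haemoglobin and crystallin genes, predicted gene models and, outside rods, the rod phototransduction list, whose free RNA could reach other cells. Genes outside the rule are marked where they appear.

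The 26 gene lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01 between genes, adjusted over the lists within a comparison, and again with an estimated correlation. With the estimated correlation only the interferon list in Müller glia and in bipolar cells of rd10 mice passed. No list that passed camera differed in sign between its median, its mean and the test. The symbols Aldoa and Ddit3 each matched 2 gene identifiers, and both identifiers were kept. Cell shares were compared by exact two-sided permutation of genotype labels within age, with 95% Wilson intervals per library. All intervals and floors cover counting error only. The overlap between models was set beside the product of list sizes and beside 40 simulations of unchanged groups against the shared WT libraries.

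The tests were tried on simulated counts with 200 changed genes of a mean count of at least 50, 50 per fold size. In the simulation of the rd10 comparison at P30 in rods (18790 genes), 10% of 2-fold, 80% of 4-fold, 98% of 8-fold and 100% of 16-fold changes were called. For P347S at P60 in rods (18748 genes), 6% of 2-fold and 66% of 4-fold changes were called. For the means over ages in rods, 2-fold changes were called at 52% in rd10 (18775 genes) and 58% in P347S (18695 genes). The lowest figure was 2% of 2-fold changes for rd10 microglia (12304 genes). No call had the wrong direction. Unchanged genes made up 4.7 to 16.8% of the calls over the comparisons, above the nominal 5% in most. A proteasome list raised 2-fold in simulated rods (18795 genes) was called with the preset correlation and missed with the estimated one.

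Replicate numbers recur across groups, so their pairing was checked by the correlation of deviations between same-numbered libraries. All 3 pairs of groups passed 0.1 in microglia, at 0.154, 0.396 and 0.238, so blocked values stand beside the microglia results, although the labels tie the numbers to no animal, litter or day. In the other 4 classes at least 1 pair stayed below 0.1. The pair of libraries within each group differed by more than sampling noise, with a chi-square per degree of freedom between 3.8 and 100.75, and none was treated as a duplicate.

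The alternatives were DESeq2 1.42.0, RLE scaling, no filter on low counts, an additive model of age and genotype, the replicate number as a block, at least 1000 genes per cell, doublets kept, equal numbers of cells per library and class, Leiden resolution 2 and clustering without marker genes for the shares, and each library of a replicated group left out in turn. An alternative without the rod clusters of low Malat1 (under 25000 CPM), a nuclear transcript whose loss can mark cells stripped of nuclei, was chosen after seeing the data. Other named classes, amacrine and pigment epithelial cells among them, were not tested gene by gene, because the tests were fixed for 5 classes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.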

Results

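The series compared single cells from eye tissue of WT mice with those of the rd10 and P347S models to find survival mechanisms that photoreceptors of different models share. In 13 libraries, 334289 cells remained after filtering. Total UMIs per library were 104395438 in WT, 99476868 in rd10 and 86367767 and 107163577 in P347S at P10. They were 65906656 in WT and 66114214 in rd10 at P18. At P30 they were 66112095 and 83176061 in WT, 56361495 in rd10 and 87514914 in P347S, and at P60 they were 113007156 and 65026113 in WT and 76975609 in P347S. The median UMI count per cell ran from 1138 in P347S at P30 to 5281 in WT at P60, replicate 1. The median share of mitochondrial UMIs in rods differed between libraries, at 16.7 and 17.8% in WT at P30, 5.99% in rd10 at P30 and 9.69% in P347S at P30. At P60 it was 2.51 and 21.7% in WT and 12.5% in P347S. Groups other than P347S at P10, WT at P30 and WT at P60 had no replicate.

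The targeted genes were looked at first. Pde6b, the rod phosphodiesterase subunit mutated in rd10, stood in rods at 984 CPM in rd10 at P10, 1306 at P18 and 911 at P30, against 936 in WT at P10, 1439 at P18 and 1211 and 1253 at P30. The rd10 mutation changes the protein rather than removing the transcript, so this level does not check the labels. Rho, the rod visual pigment, stood at 2325, 9776 and 2989 CPM in rd10 rods at P10, P18 and P30. It stood at 1050 and 1962 CPM in P347S at P10, 1973 at P30 and 1052 at P60. In WT rods it was 2369 at P10, 9547 at P18, 12470 and 11800 at P30, and 6734 and 15360 at P60. Only reads assigned to the mouse gene (ENSMUSG00000030324, GRCm38 chromosome 6, 115931748 to 115940036) were counted.

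The share of rods was compared to see how far photoreceptors were lost. Rods made up 40.02% of cells in rd10 at P30 (Wilson interval 39.4 to 40.7), 14.4% in P347S at P30 (14.1 to 14.8) and 15.2% in P347S at P60 (14.8 to 15.7). The WT libraries of 1 age lay far apart, at 21.2 and 79.8% at P30 and 3.33 and 69.8% at P60, as did P347S at P10 with 20.3 and 49.6%. At P18 the shares were 79.3% in WT and 82.2% in rd10, and at P10 they were 32.1% in WT and 45.1% in rd10. Neither model's share of rods differed from WT by more than the spread between libraries. The mean difference was 1.78 percentage points in rd10 (exact two-sided permutation p = 0.917) and -18.19 in P347S (exact permutation p = 0.481). The smallest p the design allowed was 0.083 for rd10, which cannot reach 0.05, and 0.037 for P347S. With at least 1000 genes per cell the rd10 difference turned to -7.52 points and the P347S difference became -11.95 (exact permutation p = 0.444). Cells in unnamed clusters took 54.5% of WT replicate 1 and 61.5% of P347S at P30, against 2.06 to 27.8% of the other 11 libraries, which limits any reading of shares. Cluster 30, with 96.5% of its 1971 cells from WT P60 replicate 1, stayed unnamed for its low UMI count. Its leading genes Pdzph1, Esrrb, Sntg2 and Diaph3 also led rod cluster 3, so rods of that library may be undercounted. How far the naming widened the gaps between WT libraries was not tested.

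**Figure D1:**
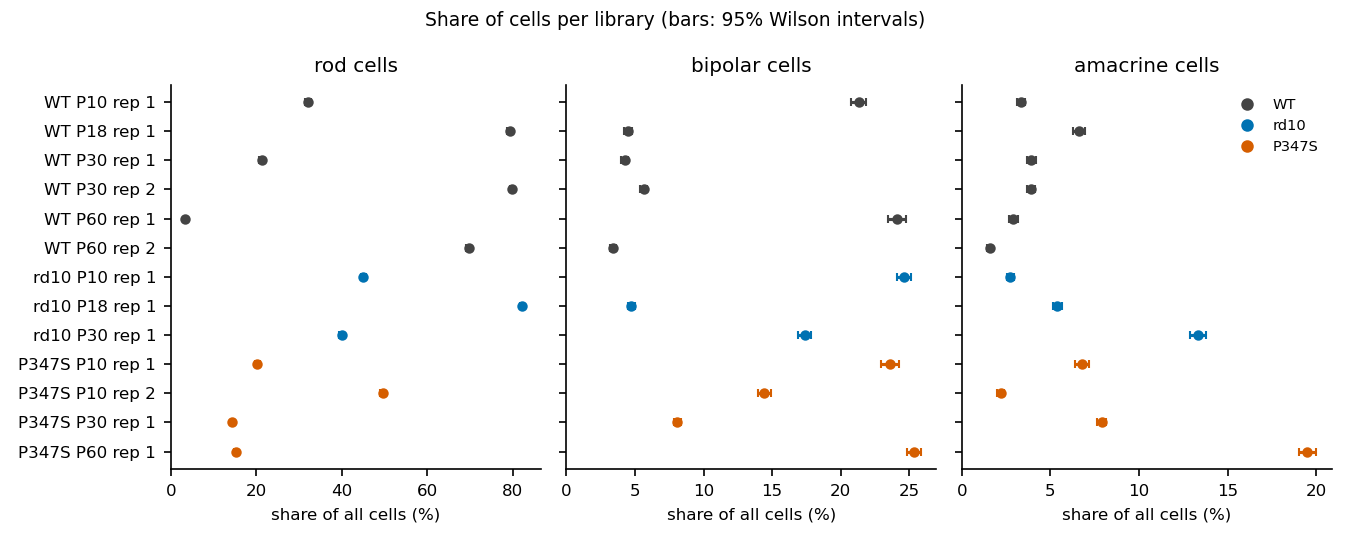
Share of all cells (percent, x axis) that were rods, bipolar cells and amacrine cells, 1 panel each, with 1 point per library (y axis) and bars for 95% Wilson intervals. Rods of the paired WT libraries sit at 21.2 and 79.8% at P30 and at 3.33 and 69.8% at P60.

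Inner retinal classes took larger shares of some mutant libraries. Amacrine cells, inhibitory interneurons, made up 13.3% in rd10 and 7.89% in P347S at P30 against 3.91% ± 0.03 in WT (SD, n = 2), and 19.5% in P347S at P60 against 2.23% ± 0.94 in WT (SD, n = 2). The mean difference was 7.46 points in P347S (exact permutation p = 0.074) and 2.54 in rd10 (p = 0.333), neither past the threshold. Bipolar cells, which carry photoreceptor signals inward, differed by 5.32 points in rd10 (exact permutation p = 0.083) and 4.15 in P347S (p = 0.556). With at least 1000 genes per cell the difference was 12.92 points for amacrine cells in P347S (exact permutation p = 0.074), and 8.51 in rd10 (p = 0.083) and 7.39 in P347S (p = 0.185) for bipolar cells. The exact permutation p was 0.25 and 0.815 for Müller glia, 0.333 and 0.778 for microglia, 0.5 and 0.481 for cones and 0.417 and 0.333 for pigment epithelium, in rd10 and P347S. Pigment epithelial cells made up 3.34 and 0.786% of WT at P30, 0.609% of rd10 and 0.098% of P347S, and 2.21 and 1.40% of WT against 0.251% of P347S at P60.

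Maturation of WT rods was measured as the reference for the age-matched comparisons. Between P10 and P60, Guca1a, an activator of the guanylate cyclase of photoreceptors, rose from 38.6 to 1876 CPM (log2 fold change 5.60 ± 0.71, adjusted p = 0.00241), and Guca1b rose by 4.98. Fabp7, a fatty acid binding protein of progenitors, fell from 309 to 5.05 CPM (-5.45 ± 0.68, adjusted p = 0.00224). The largest rises by the fixed rule were Slc22a29 (7.66), Traf3ip3 (6.80), Sh2d1a (6.48), Slc17a1 (6.04), Guca1a and Rpe65 (5.42), and the largest falls Kif19a (-5.97), Fabp7, Gpc5 (-5.42), Grm7 (-4.71), Agbl4 (-4.44) and Ptpro (-4.33). Pigment epithelial cells, which express Rpe65, made up 0.160% of cells at P10 and 2.21 and 1.40% at P60. In all, 492 genes rose and 371 fell of 19317 tested. Of 26 rod phototransduction genes, 7 rose over all genes and 11 when adjusted over the list alone, with 25 above 0 (median 1.07, adjusted p = 8.21e-09, and 0.52 as adjusted p with an estimated correlation).

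Stress and metabolic lists also differed with age in WT rods. Of 20 heat shock genes, which encode protein folding helpers, 3 fell over all genes and 13 when adjusted over the list alone (median -1.59, adjusted p = 8.39e-08), Hsp90ab1 by -2.65 ± 0.62. Of 25 glycolysis genes 4 rose (median 0.92, adjusted p = 5.55e-05), Hk2 by 2.44, while 43 of 46 nuclear genes of oxidative phosphorylation lay below 0 (median -0.54, adjusted p = 9.15e-05) and all 13 mitochondrially encoded genes above it (median 2.12, adjusted p = 0.0175). This rise came mostly from WT P60 replicate 2, where the median share of mitochondrial UMIs was 21.7%, against 2.51% in replicate 1 and 3.11% at P10, and cannot be ascribed to age. Of 26 interferon and antigen presentation genes 10 rose (median 2.22, adjusted p = 8.21e-09). Lists of other cells moved with them: 10 of 29 Müller reactivity genes, 10 of 22 Müller homeostasis genes and 5 of 15 lens crystallins rose (adjusted p = 3.37e-08, 8.21e-09 and 1.38e-08). Of the 26 lists 10 passed upward and 5 downward, among the former those of complement and microglial disease genes. With an estimated correlation no list passed (adjusted p = 0.52 for the smallest). Without WT P60 replicate 1 the 863 calls became 1552.

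At P10, before rod loss in rd10, no gene passed in rd10 rods (edgeR quasi-likelihood test, 0 of 19317, 92 at unadjusted p below 0.05, 0 by DESeq2). Of 26 interferon and antigen presentation genes, 17 lay above 0 (median 0.16, adjusted p = 0.00537, and adjusted p = 0.989 with an estimated correlation). Of 22 Müller homeostasis genes, 17 lay below 0 (median -0.22, adjusted p = 0.0281, and 0.989 as adjusted p with an estimated correlation). Rods of both genotypes at P10 lay mostly in 1 cluster led by Fabp7, Hspa1a and Hspa1b, with 98.1% of WT and 98.3% of rd10 rods. Without WT P30 replicate 1 or 2 the count became 4 or 3.

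At P18, around the onset of rod death in rd10 mice, no gene passed in rods (0 of 19317, 188 at unadjusted p below 0.05, 8 by DESeq2), but fixed lists stood apart together. All 26 interferon genes lay above 0 (median 1.52, 14 past the threshold adjusted over the list alone, adjusted p = 6.3e-60), as did 28 of 29 Müller reactivity genes (median 1.56, 15 adjusted over the list alone, adjusted p = 6.41e-78). Of 30 genes of survival cytokines and STAT3 signalling, 27 lay above 0 (median 0.98, 7 adjusted over the list alone, adjusted p = 1.09e-38). Examples are Serpina3n, an acute phase protease inhibitor, at 11.5 CPM in rd10 and 0.410 in WT (4.79 ± 0.60, adjusted p = 0.121), Edn2, a vasoactive peptide released by stressed photoreceptors, at 5.53, and Bcl3, a cofactor of NF-κB, at 4.33. Complement genes (13 of 16 above 0, median 0.90, adjusted p = 1.02e-11), microglial disease genes (24 of 26, median 0.56, adjusted p = 5.54e-12), immediate early genes (20 of 24, median 0.29, adjusted p = 0.0126) and non-apoptotic death genes (16 of 19, median 0.23, adjusted p = 0.000333) were also high. Cilium genes (25 of 26 below 0, median -0.20, adjusted p = 0.000956) and phototransduction genes (22 of 26, median -0.19, adjusted p = 0.0131) were low. The adjusted p with an estimated correlation was 0.0865 for the interferon and Müller reactivity lists, 0.115 for the survival list and above 0.05 for the rest. Several of these lists hold genes of other cells, and the interferon and Müller reactivity lists were also high in rd10 Müller glia over the ages. RNA from other cells was not tested for these lists and cannot be told from a response of rods. Each genotype had 1 library at this age, and the WT library nearly lacked Xist, so sex cannot be told from genotype. Dpp10 stood at 258 CPM in rd10 and 23.0 in WT, a gene named here because of its values at P30. The count of 0 became 8 and 6 without WT P30 replicates 1 and 2 and 5 and 7 without WT P60 replicates 1 and 2.

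At P30, 66 genes rose and 7 fell in rd10 rods. In the 40 simulations of an unchanged group, 0 to 12 rises and 0 to 11 falls were called. The 7 falls lay within that range and the rises above it. Dpp10 (ENSMUSG00000036815, chromosome 1, 123321471 to 124045559), a subunit that modulates potassium channels, reached 3988 CPM against 23.5 ± 4.3 in WT (SD, n = 2), a log2 fold change of 7.40 ± 0.66 (adjusted p = 0.00437). Zbtb7c (5.35 ± 0.85), Slc2a13, a proton-coupled inositol transporter (4.64 ± 0.64), Fhad1 (4.62 ± 0.65) and Myo5b, a vesicle motor (4.22 ± 0.70), followed. Fgf2os (5.65 ± 0.56, adjusted p = 0.00694) overlaps Fgf2 on the opposite strand (chromosome 3, 37335332 to 37349740 against 37348346 to 37410108). With the use of strand unstated, reads in the shared stretch of 37348346 to 37349740 cannot be told apart. Reads outside that stretch lie in only 1 of the 2 genes. Fgf2, a growth factor that protects photoreceptors, rose from 14.4 ± 1.8 (SD, n = 2) to 202 CPM (3.82 ± 0.53, adjusted p = 0.0162), and Bcl3 rose by 4.96 ± 0.76 (adjusted p = 0.0307). Rgr (-2.81 ± 0.50, adjusted p = 0.0424) and Rpe65 (-2.13 ± 0.39, adjusted p = 0.0487), visual cycle genes of pigment epithelium and glia, fell, while pigment epithelial cells were 0.609% of this library and 3.34 and 0.786% of WT. Rods of this library lay mostly (88.6%) in a cluster led by Dpp10, Fgf2os, Antxr2 and Mctp1, which had 4 of 15 rod markers, and WT rods at P30 in 2 others. Within the Dpp10 cluster, Mctp1 stood at 7.44 CPM in rods of this library against 764.81 in P347S rods at P60. Its lead there does not describe rd10 rods.

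The 30 survival genes included 2 rises over all genes and 5 when adjusted over the list alone in rd10 rods at P30 (18 above 0, median 0.14, adjusted p = 0.00145), with Edn2 at 3.42 ± 0.63 (adjusted p = 0.0508) just short. Of 46 nuclear oxidative phosphorylation genes, all lay below 0 and none passed (median -1.14, adjusted p = 3.02e-11), as did all 13 mitochondrially encoded ones (median -1.63, adjusted p = 0.000755), Ndufs2 at -1.70 and mt-Atp6 at -2.13 ± 1.16. Phototransduction genes were below 0 in 23 of 26 (median -0.999, adjusted p = 9.35e-07), with Gngt1 at -2.84 ± 0.84 (adjusted p = 0.225) and Nrl, the rod-specifying factor, at -1.76 ± 0.56 (adjusted p = 0.261). Lists of the proteasome (30 of 31 below 0, median -0.74), glycolysis (23 of 25, -0.74), endoplasmic reticulum unfolded protein response (22 of 25, -0.75), heat shock (18 of 20, -0.72), integrated stress response (20 of 24, -0.56) and antioxidant response (20 of 23, -0.48) were low as well (adjusted p = 4.41e-05 to 0.00705). Interferon genes (20 of 26 above 0, median 0.78, adjusted p = 0.000167) and Müller reactivity genes (2 of 29 rose, median 0.19, adjusted p = 0.0157) were high, and Müller homeostasis genes (1 of 22 fell, median -0.49), cone phototransduction genes (13 of 15 below 0, median -0.79) and immediate early genes (18 of 24 below 0, median -0.76) low (adjusted p = 0.00523 to 0.0134). Lens crystallins, markers of lens cells, rose in 5 of 15 (median 1.51, adjusted p = 4.18e-18). Crygb stood at 68.5 CPM in these rods and 16.5 in Müller glia of the same library, and reads of the gamma crystallins can be shared between near-identical copies. The lists of rod synapse (median -0.18, adjusted p = 0.884), apoptosis promoting (-0.30, 0.274), apoptosis restraining (-0.04, 0.744) and autophagy and lysosome genes (-0.29, 0.131) did not pass. With an estimated correlation no list passed (adjusted p = 0.629 for all 16). The median mitochondrial share of these rods was 5.99% against 16.7 and 17.8% in WT.

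The 73 calls in rd10 rods at P30 became 38 without P347S P10 replicate 2, 646 without WT P60 replicate 1 and 576 without WT P60 replicate 2. Without P347S P10 replicate 2, Zbtb7c (adjusted p = 0.0514), Rgr (0.103) and Rpe65 (0.0859) did not pass. Rgr was also lost without P347S P10 replicate 1 (0.0752), and Rpe65 without that library (0.0655) and without WT P30 replicate 1 (0.113) or 2 (0.0685). Over 14 alternatives the adjusted p of these 3 genes ran from 4.42e-33 to 0.236, while that of Dpp10 ran from 2.16e-40 to 0.0257. Over the ages no gene passed in rd10 rods by edgeR (0 of 19317, 548 at unadjusted p below 0.05, 44 by DESeq2), which became 36, 30, 28 and 41 without WT P30 replicates 1 and 2 and WT P60 replicates 1 and 2. In this mean, 24 of 26 interferon genes lay above 0 (median 0.72, 13 adjusted over the list alone, adjusted p = 9.88e-30), as did 26 of 30 survival genes (median 0.39, 7 adjusted over the list alone, adjusted p = 3.02e-18), while all 26 phototransduction genes lay below 0 (median -0.40, adjusted p = 3.37e-07). Microglial homeostatic genes, which mark microglia at rest, lay above 0 in 12 of 15 (median 0.22, adjusted p = 0.0255). In all, 8 lists passed upward, the crystallins and the lists of Müller reactivity and microglial disease among them, and 9 downward. With an estimated correlation the smallest adjusted p was 0.368.

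In P347S rods at P10, the earliest age sampled, 3 genes passed. Trhde (ENSMUSG00000050663, chromosome 10, 114398823 to 114802307, minus strand), a peptidase that degrades thyrotropin-releasing hormone, stood at 129 and 163 CPM in P347S against 2.98 in WT and 2.18 in rd10 (5.61 ± 0.47, adjusted p = 0.00226). By raw UMIs the rise over WT was 51.4-fold (39.4 to 68.6). The other 2, named although predicted genes lie outside the rule and so chosen after their values were seen, lie at the same place. 4930473D10Rik (114757747 to 114785104, plus strand) overlaps Trhde on the opposite strand, so their reads cannot be told apart for certain, and held 459 UMIs against 4 in WT, a ratio of 59.5 (23.1 to 219). Gm31182 (114875007 to 114885131) held 1002 UMIs against 0 in WT, 173-fold higher with a floor of 3 counts set on the WT library, and 141-fold at the lower end of the counting interval. Most rods of P347S replicate 2 (96.3%) lay in a cluster of their own, and those of replicate 1 in that of WT and rd10 (90.8%).

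**Figure D2:**
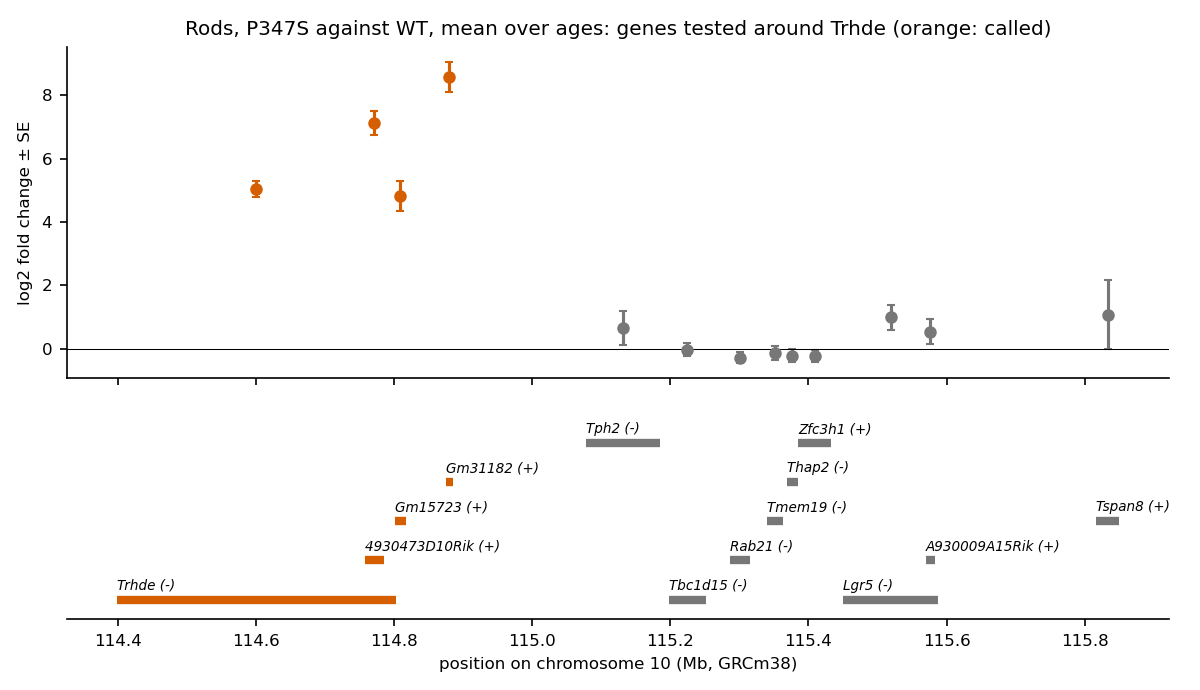
Log2 fold change in rods of P347S against WT over the ages (y axis, points with standard errors) of the 13 genes tested around Trhde by position on chromosome 10 (GRCm38, x axis in megabases), with the genes drawn as bars below. The 4 called genes, Trhde (5.04), 4930473D10Rik (7.14), Gm15723 (4.81) and Gm31182 (8.58), lie side by side, and the other 9 had adjusted p of at least 0.237.

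Several fixed lists were low in P347S rods at P10. All 20 heat shock genes lay below 0 (median -1.01, adjusted p = 1.36e-09), and so did 21 of 24 integrated stress response genes, targets of translational arrest (median -0.78, adjusted p = 1.36e-09). Microglial disease genes (24 of 26 below 0, median -0.57, adjusted p = 1.47e-05), apoptosis promoting genes (18 of 22, -0.34, adjusted p = 0.00381), proteasome genes (29 of 31, -0.25, adjusted p = 0.0232), autophagy and lysosome genes (22 of 30, -0.28, adjusted p = 0.0467), survival genes (22 of 30, -0.28, adjusted p = 0.0467) and crystallins (12 of 15, -0.88, adjusted p = 0.0203) were low too. Phototransduction genes (21 of 26 above 0, median 0.31, adjusted p = 0.0155) and cilium genes (20 of 26, 0.34, adjusted p = 0.0467) were high. In all, 2 lists passed upward and 11 downward, those of Müller reactivity and homeostasis and of immediate early genes included. None passed with an estimated correlation (adjusted p = 0.616 for the smallest). Most WT and rd10 rods of this age lay in a cluster led by Hspa1a and Hspa1b, near-identical copies that share reads. This cluster also held 90.8% of the rods of P347S replicate 1 but 2.0% of those of replicate 2. It therefore does not separate the genotypes. The 3 calls became 26 and 6 without WT P30 replicates 1 and 2, 34 without either WT P60 library, and 2 without P347S P10 replicate 2.

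At P30, 54 genes rose and 8 fell in P347S rods. The 40 simulations of an unchanged group gave 0 to 10 rises and 0 to 7 falls, so the falls barely passed that range. Mctp1, a calcium-binding membrane protein (ENSMUSG00000021596, chromosome 13, 76384535 to 77031810), rose from 3.23 to 386 CPM (6.96 ± 0.64, adjusted p = 0.000962), and microglia of WT at P30 held it at 343 CPM. Zbtb7c (5.01 ± 0.84), Fgf2os (4.98 ± 0.56), Fhad1 (4.52 ± 0.65), Dpp10 (4.51 ± 0.60, adjusted p = 0.0122) and Edn2 (4.50 ± 0.64, adjusted p = 0.0178) came next by the rule, and Bcl3 (4.87, adjusted p = 0.027) and Fgf2 (3.26 ± 0.52, adjusted p = 0.0295) rose too. Rgr (-3.77 ± 0.54), Rpe65 (-3.43 ± 0.43), Rdh5 (-2.58 ± 0.45) and Ttr, a retinol carrier of pigment epithelium (-3.17 ± 0.50), fell, and pigment epithelial cells made up 0.098% of this library. Ttr in Müller glia stood at 57.3 CPM against 359 and 158 in WT. Rho stood at 1973 CPM against 12130 ± 476 (SD, n = 2), a log2 fold change of -2.62 ± 0.77 that did not pass (adjusted p = 0.438). In this library 65.4% of rods lay in the cluster led by Dpp10 and Fgf2os.

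Survival genes rose in 3 of 30 over all genes and 5 adjusted over the list alone in P347S rods at P30 (25 above 0, median 0.50, adjusted p = 2.59e-09). Interferon genes (22 of 26 above 0, median 0.66, adjusted p = 3.11e-06), complement genes (10 of 16, 0.53, adjusted p = 0.0188) and Müller reactivity genes (3 of 29 rose, 0.59, adjusted p = 2.73e-09) were also high. Phototransduction genes were below 0 in 25 of 26 (median -0.99, adjusted p = 5.75e-12), photoreceptor transcription factors in 13 of 14 (-0.76, adjusted p = 3.11e-06), with Prdm1 at -1.80 ± 0.41 (adjusted p = 0.175), cilium genes in 19 of 26 (-0.33, adjusted p = 0.0188), mitochondrially encoded genes in 13 of 13 (-1.12, adjusted p = 0.0031) and crystallins in 12 of 15 (-0.92, adjusted p = 0.0133). With an estimated correlation the smallest adjusted p was 0.568. The 62 calls became 35 without P347S P10 replicate 2, 119 and 135 without WT P60 replicates 1 and 2. Without P347S P10 replicate 2, Zbtb7c (adjusted p = 0.0594), Fhad1 and Rgr (both 0.0508), Ttr (0.0813) and Rdh5 (0.0971) did not pass. Ttr (0.0639) and Rdh5 (0.0741) were also lost without P347S P10 replicate 1, and Rdh5 without WT P30 replicate 1 (0.107). Over 14 alternatives the adjusted p of these 5 genes ran from 4.68e-29 to 0.158, and that of Dpp10 from 4.65e-18 to 0.0479.

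To find changes that the models share, calls at P30 were overlapped. In both models 26 genes rose and 4 fell, and none went in opposite directions. Among genes that the rule admits, which leaves out predicted genes, the rises with the largest smaller change were Zbtb7c, Fgf2os, Bcl3, Fhad1, Dpp10, Scube1 (4.33 in rd10 and 4.16 in P347S), Slc2a13 (4.64 and 4.08), Myo5b (4.22 and 3.92), Prtg (3.86 and 4.06) and Togaram2 (5.07 and 3.82). Fgf2 was among the 26, at 3.82 and 3.26. The falls were Rgr, Rpe65, Glb1l3 (-4.61 and -5.05) and the predicted gene Gm14091. Independent lists would share 0.185 rises and 0.0029 falls, and simulated unchanged groups against the same WT libraries shared 0.275 and 0.15 on average and at most 3 and 1 in 40 simulations. The log2 fold changes correlated at 0.453 across genes, which are not independent, against 0.251 simulated. Their covariance was 0.560 against 0.218 simulated, a difference of 0.342. The 2 WT libraries were too few to leave 2 for each model, so both models were set against the same controls. The simulations held this sharing with independent noise per gene. Shifts of many genes together in the shared controls may still add to the excess. The simulations drew each gene independently, so they cannot reproduce shifts that many genes make together. The WT rods also differed from those of both models in median mitochondrial share, at 16.7 and 17.8% against 5.99% in rd10 and 9.69% in P347S. How much of the overlap comes from such differences between libraries was not tested. The count of 30 became 13 without P347S P10 replicate 2, 85 without WT P60 replicate 1 and 98 without WT P60 replicate 2.

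**Figure D3:**
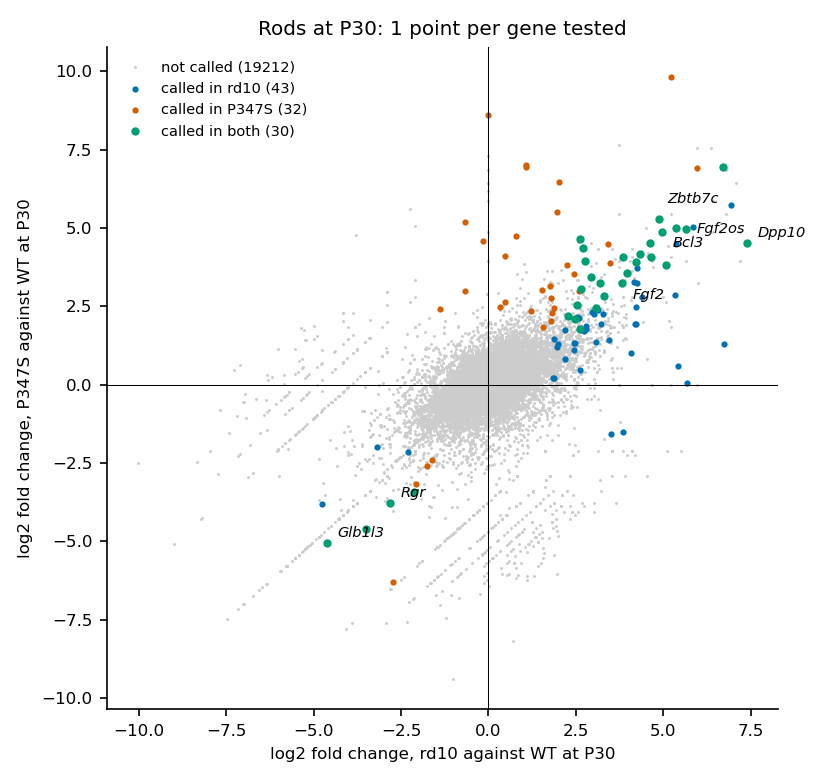
Log2 fold change against WT at P30 in rods for rd10 (x axis) and P347S (y axis), each point a gene. Of the genes tested, 30 passed in both models, 43 in rd10 alone and 32 in P347S alone, and the 30 lie in the quadrants where both models moved the same way.

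**Figure D4:**
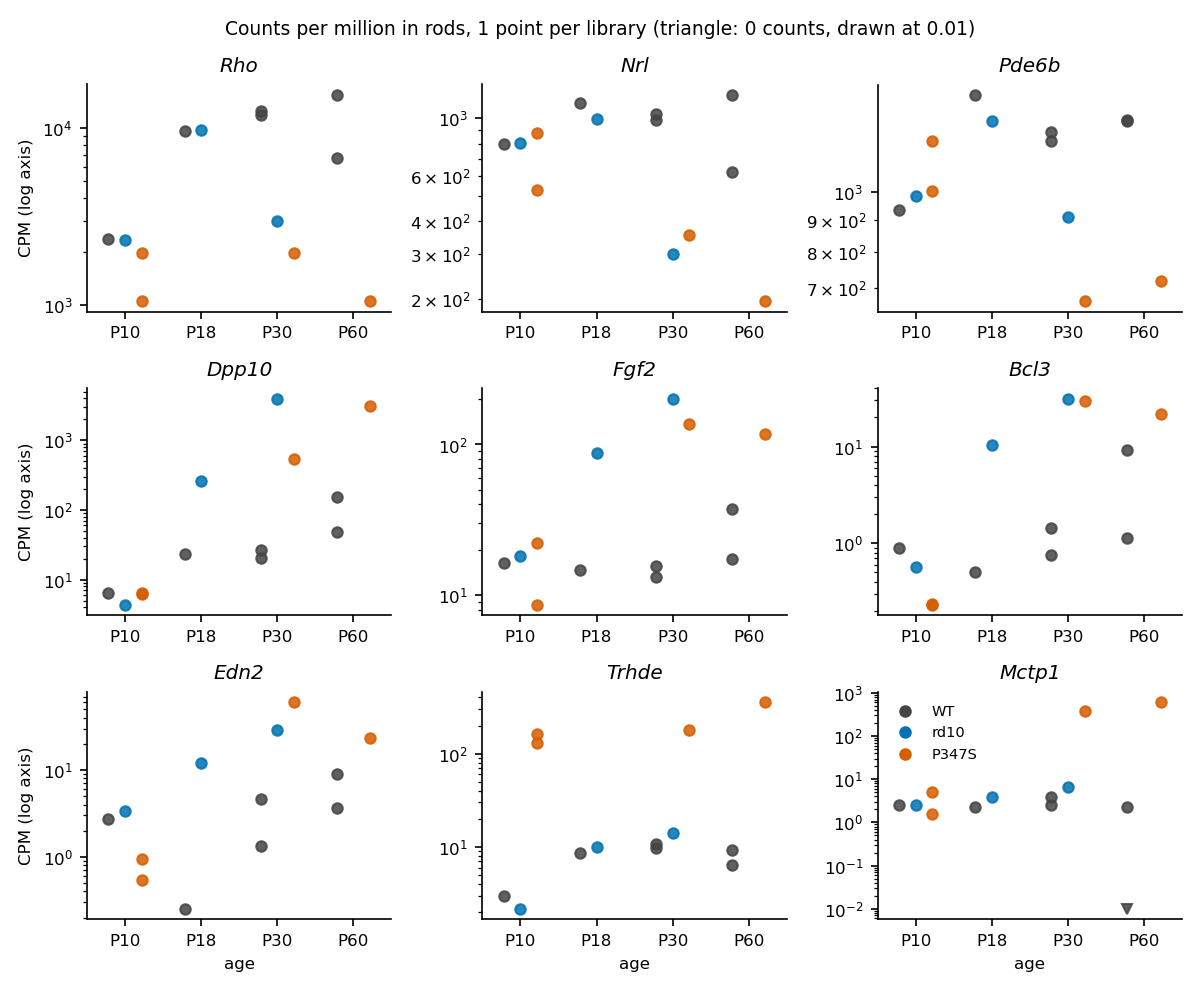
Level of 9 genes in rods (CPM, logarithmic y axis) by age (x axis), each point a library coloured by genotype, with a triangle at 0.01 for a library with 0 counts. Dpp10 ran from 4.31 CPM in rd10 at P10 to 3988 in rd10 at P30, and Fgf2 stood at 202 CPM in rd10 and 137 in P347S at P30 against 15.6 and 13.1 in WT.

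At P60, 110 genes rose and 19 fell in P347S rods. Mctp1 reached 607 CPM against 1.11 (8.29 ± 0.72, adjusted p = 0.000799), Trhde 356 against 7.82 (5.39 ± 0.37, adjusted p = 0.000293) and Dpp10 3083 against 102 ± 76 (SD, n = 2), a change of 4.97 ± 0.61. Grem2, an antagonist of bone morphogenetic proteins, rose by 5.59 ± 0.55, Slc2a13 by 4.35 ± 0.66 and Col25a1 by 4.15 ± 0.45. Rgr (-3.58 ± 0.53), Rpe65 (-2.95 ± 0.42), Arl4d (-2.69 ± 0.40), Rdh5 (-2.48 ± 0.46), Sh2d1a (-2.45 ± 0.43) and Sdhd (-2.34 ± 0.45) fell, beside 0.251% of pigment epithelial cells against 2.21 and 1.40% in WT. Rho stood at 1052 CPM against 6734 and 15360 in WT (-3.39 ± 0.81, adjusted p = 0.0774) and Nrl at 196 CPM (-2.24 ± 0.58, adjusted p = 0.0992), neither past the threshold. Most P347S rods (86.2%) lay in the cluster led by Dpp10, which also held 12.8% of the rods of WT replicate 1. Another cluster held 82.3% of the rods of WT replicate 1 and 45.6% of those of replicate 2, with 39.0% of the latter in yet another.

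All 26 phototransduction genes lay below 0 in P347S rods at P60 (median -1.34, 14 adjusted over the list alone, adjusted p = 1.41e-11), as did all 14 photoreceptor transcription factors (median -0.83, 3 adjusted over the list alone, adjusted p = 5.05e-05). Survival genes were above 0 in 23 of 30 (median 0.64, 5 adjusted over the list alone, adjusted p = 0.00226), with Fgf2 at 2.23 ± 0.54 (adjusted p = 0.0819) and A2m, a protease trap of reactive glia, at 2.39 ± 0.48 (adjusted p = 0.0501). Proteasome (29 of 31 below 0, median -0.48), glycolysis (22 of 25, -0.64), unfolded protein response (22 of 25, -0.60), cilium (21 of 26, -0.45) and heat shock genes (16 of 20, -0.52) were low (adjusted p = 0.00173 to 0.0323). Müller reactivity genes (19 of 29 above 0, 0.56, adjusted p = 0.00306) and all 15 crystallins (median 2.46, adjusted p = 7.72e-11) were high. With an estimated correlation no list passed (adjusted p = 0.657 for the smallest). The 129 calls became 47 and 29 without P347S P10 replicates 1 and 2, 479 and 386 without WT P30 replicates 1 and 2, and 1111 and 651 without WT P60 replicates 1 and 2. Without P347S P10 replicate 2, Slc2a13 (adjusted p = 0.0655), Rgr (0.0644), Arl4d (0.0617), Rdh5 (0.0828), Sh2d1a (0.073) and Sdhd (0.0836) did not pass. Rdh5 (0.0649), Sh2d1a (0.06) and Sdhd (0.0715) were lost without P347S P10 replicate 1, and Sdhd (0.0576) without WT P60 replicate 2. Over 14 alternatives the adjusted p of these 6 genes ran from 1.14e-20 to 0.358, and that of Trhde from 7.71e-31 to 0.00184. With RLE scaling the split of calls was 279 to 35.

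Over the ages, 185 genes rose and 75 fell in P347S rods. Mctp1 (5.15 ± 0.43, adjusted p = 0.000295), Trhde (5.04 ± 0.25, adjusted p = 7.55e-06) and Rtkn2, a Rho GTPase effector (3.81 ± 0.22, adjusted p = 1.36e-05), rose most among genes that the rule admits, while the predicted genes beside Trhde rose by 4.81 to 8.58. Dpp10 (3.15 ± 0.38), Zbtb7c (2.80 ± 0.52) and Slc2a13 (2.76 ± 0.40) rose as well, as did Fgf2 (1.79 ± 0.32) and the complement gene C4b (2.01 ± 0.40). Rho fell by 2.22 on the log2 scale (± 0.42, adjusted p = 0.0324), from 8516 to 1510 CPM. Hopx (-2.19 ± 0.43), Rgr (-2.17 ± 0.28), Rpe65 (-1.58 ± 0.23), Tnfaip3, a brake on NF-κB (-1.55 ± 0.29), Ttr (-1.53 ± 0.25) and the photoreceptor factor Prdm1 (-1.11 ± 0.22) fell. Slc16a1, a lactate transporter, changed by -1.39 ± 0.23. Heat shock genes were below 0 in 20 of 20 (median -0.52, adjusted p = 0.000114), phototransduction genes in 24 of 26 (-0.64, adjusted p = 1.42e-08), integrated stress response genes in 20 of 24 (-0.34, adjusted p = 0.00163) and proteasome genes in 29 of 31 (-0.29, adjusted p = 0.00623), and survival genes above 0 in 24 of 30 (0.25, adjusted p = 0.00259). In all, 2 lists passed upward, the other being Müller reactivity, and 8 downward. The smallest adjusted p with an estimated correlation was 0.708. An additive model of age and genotype called 49 genes in place of 260 and lost Mctp1 (adjusted p = 0.073), Dpp10 (0.188), Rho (0.128) and 7 of the other ranked genes. Over 15 alternatives the adjusted p ran from 1.26e-61 to 0.073 for Mctp1, 2.93e-22 to 0.188 for Dpp10, 1.24e-10 to 0.128 for Rho and 1.11e-82 to 0.000192 for Trhde.

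The count of 260 for P347S rods over the ages became 131 and 95 without P347S P10 replicates 1 and 2, 413 without WT P30 replicate 1, and 1523 and 872 without WT P60 replicates 1 and 2. Rho did not pass without P347S P10 replicate 1 (adjusted p = 0.102) or 2 (0.077), Zbtb7c and Ttr not without replicate 1 (both 0.0619), and Ttr (0.0701) and Hopx (0.0827) not without replicate 2. Over 15 alternatives the adjusted p of these 4 genes ran from 2.8e-24 to 0.25. With RLE scaling the split was 263 rises to 87 falls.

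The models were compared with each other at the ages both had. At P10, Trhde (6.06 ± 0.48, adjusted p = 0.00132) and its neighbours 4930473D10Rik and Gm31182 were higher in P347S than in rd10 rods, and no gene was lower. At P30, Trhde stood at 177 against 14.1 CPM (3.66 ± 0.44, adjusted p = 0.0391), Dock8, a regulator of the actin cytoskeleton, at 60.8 against 4.82 (3.66 ± 0.45, adjusted p = 0.0391), and Gm31182 was the third. All 20 heat shock genes (median -0.99, adjusted p = 1.06e-10) lay lower in P347S at P10, as did the integrated stress response list (-0.86, adjusted p = 1.06e-12) and 21 of 26 interferon genes (-0.61, adjusted p = 0.000169). At P30, 45 of 46 nuclear oxidative phosphorylation genes (median 0.93, adjusted p = 2.8e-11) and 29 of 31 proteasome genes (0.67, adjusted p = 2.72e-06) lay higher in P347S, and crystallins lower (-2.37, 12 adjusted over the list alone, adjusted p = 3.71e-32). Of the 26 lists, 1 passed upward and 12 downward at P10, and 7 and 3 at P30, so the shifts were not particular to the lists named. The adjusted p with an estimated correlation was 0.578 for the smallest at P10 and 0.679 at P30. The 3 calls at P10 became 32 and 11 without WT P30 replicates 1 and 2 and 26 and 25 without WT P60 replicates 1 and 2. The 3 at P30 became 0 without P347S P10 replicate 2 (Trhde and Dock8 adjusted p = 0.0694, and 9.79e-10 to 0.537 over 14 alternatives), 16 and 15 without WT P30 replicates 1 and 2, 11 without either WT P60 library, and 6 without P347S P10 replicate 1.

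In cones, the photoreceptors that outlive rods, 45 genes rose and 7 fell over the ages in P347S. Mctp1 (4.89 ± 0.38, adjusted p = 0.000391), Cadps2, a factor of vesicle release (4.16 ± 0.37, adjusted p = 0.000667), Me3 (3.20 ± 0.32), Dpp10 (2.97 ± 0.37), Trhde (2.50 ± 0.21) and AA465934 (2.47 ± 0.29) rose most among genes that the rule admits. Fgf2 rose by 2.42 ± 0.27 in P347S (adjusted p = 0.00189) and from 5.29 to 49.4 CPM, 2.60 ± 0.32, in rd10 (adjusted p = 0.0375), where Mctp1 was the only other call. The ratio of Fgf2 to Rho in cones of mutant libraries was 1.81 times that in rods. Moxd1 (-1.25 ± 0.22), Ddit4 (-1.22 ± 0.21), Cdh12 (-1.19 ± 0.20) and Cep250 (-1.05 ± 0.20) fell in P347S.

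Survival genes in cones were above 0 in 23 of 27 in P347S (1 rose, median 0.38, adjusted p = 0.0025) and 19 of 27 in rd10 (1 rose, 0.28, adjusted p = 9.04e-06). Heat shock (19 of 20 below 0, median -0.25) and glycolysis genes (17 of 25, -0.30) were low in P347S (adjusted p = 0.0025 for both), and Müller reactivity (20 of 26 above 0, 0.53, adjusted p = 2.63e-08), interferon (17 of 21, 0.49, adjusted p = 0.000538) and mitochondrially encoded genes (median -0.35, adjusted p = 0.00185) differed in rd10. All 26 rod phototransduction genes lay below 0 in rd10 cones (-0.38, adjusted p = 2.72e-05). In all, 6 lists passed upward and 4 downward in rd10, and 1 and 4 in P347S. Lists of other cells moved with them in rd10 cones, as complement genes (6 of 8 above 0, median 0.85), microglial disease genes (15 of 22, 0.20) and lens crystallins (11 of 13, 1.08) were high (adjusted p = 0.0176, 0.0176 and 0.0337). No list passed with an estimated correlation (adjusted p = 0.827 in rd10 and 0.869 in P347S). The 52 calls in P347S became 96 and 166 without P347S P10 replicates 1 and 2, 16 and 13 without WT P30 replicates 1 and 2 and 84 without WT P60 replicate 2. Without either WT P30 library Moxd1, Ddit4, Cdh12 and Cep250 did not pass (adjusted p = 0.199 to 0.269), and Cep250 (0.0516) not without WT P60 replicate 2. Their adjusted p ran from 0.000235 to 0.269 over 14 alternatives. The 2 calls in rd10 became 11 and 8 without P347S P10 replicates 1 and 2, 4 without either WT P60 library and 0 without either WT P30 library, where Fgf2 had adjusted p = 0.304 and 0.421, within 2.02e-08 to 0.562 over 14 alternatives.

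In Müller glia, the radial support cells, interferon-stimulated genes rose in rd10. Ifit1, which binds viral RNA, rose from 4.15 to 60.9 CPM (4.45 ± 0.36, adjusted p = 0.0316), Isg15, a ubiquitin-like modifier, by 3.77 ± 0.33, Rsad2 by 3.64 ± 0.37, Ifit3 by 3.09 ± 0.30, Bst2 by 2.70 ± 0.21 and Oasl2 by 2.24 ± 0.21. Isg15 stood at 26.8, 56.7 and 181 CPM in rd10 at P10, P18 and P30, against 4.22, 1.63 and 15.3 ± 7.0 (SD, n = 2) in WT. Of 26 interferon and antigen presentation genes 6 rose over all genes and 21 adjusted over the list alone, with 26 above 0 (median 1.68, adjusted p = 1.15e-121), and this list passed with an estimated correlation too (adjusted p = 0.0429). Dpp10 rose by 3.73 ± 0.33 in rd10 and 3.70 ± 0.27 in P347S, at a ratio to Rho 0.35 times that in rods. In P347S, AA465934 and Antxr2, neither of them ranked by the rule, rose too. AA465934 was higher in all 5 classes of P347S at P10. Hopx fell in P347S from 295 to 141 CPM (-1.72 ± 0.16, adjusted p = 0.0461).

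**Figure D5:**
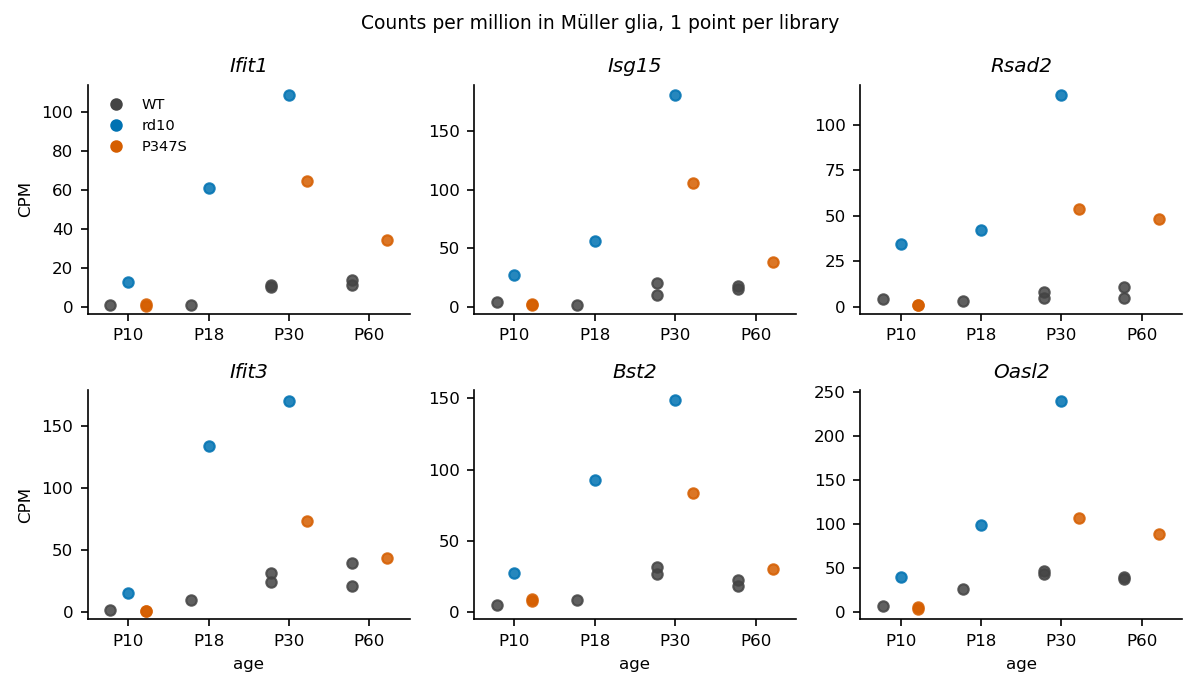
Level of 6 interferon-stimulated genes in Müller glia (CPM, y axis) by age (x axis), each point a library coloured by genotype. Isg15 stood at 26.8 to 181 CPM in rd10 libraries and reached 106 CPM in P347S at P30.

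Müller reactivity genes, raised in gliosis, were above 0 in 27 of 29 in rd10 Müller glia (median 1.35, 9 adjusted over the list alone, adjusted p = 1.64e-38) and 20 of 29 in P347S (0.79, adjusted p = 3.38e-08). Gfap, an intermediate filament, stood at 2.45 ± 0.34 in rd10 (adjusted p = 0.138) and 2.13 ± 0.30 in P347S (adjusted p = 0.111), and Timp1 at 4.05 ± 0.45 in rd10 (adjusted p = 0.0622). Survival genes were above 0 in 22 of 29 in rd10 (0.56, adjusted p = 8.98e-13) and complement genes in 11 of 13 (0.85, adjusted p = 9.22e-05). Müller homeostasis genes lay below 0 in 17 of 21 (-0.28, adjusted p = 0.0299). The other lists to pass in rd10, all upward, were cone phototransduction (14 of 15 above 0, 0.72, adjusted p = 1.85e-07), microglial disease (19 of 24, 0.28, adjusted p = 0.000838), apoptosis promoting (12 of 20, 0.10, adjusted p = 0.0204) and non-apoptotic death genes (14 of 19, 0.16, adjusted p = 0.0246), which makes 8 upward and 1 downward, against 5 and 3 in P347S. In P347S the interferon list was above 0 in 24 of 26 (0.70, adjusted p = 2.22e-11), and all 20 heat shock genes were below 0 (-0.51, adjusted p = 0.000427). With an estimated correlation the reactivity lists had adjusted p = 0.382 and 0.82, and no list but interferon in rd10 passed.

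The 7 calls in Müller glia of rd10 were all lost without either WT P30 library (count 0, adjusted p = 0.12 to 0.219 for the 6 ranked genes, within 8.61e-30 to 0.874 over 14 alternatives), and Isg15, Rsad2 and Ifit3 also without either P347S P10 library (0.0676 to 0.129). The 4 calls in P347S fell to 0 without either P347S P10 library, either WT P30 library or WT P60 replicate 1, and to 1 without WT P60 replicate 2, over which Dpp10 had adjusted p = 0.0512 to 0.181 where lost and Hopx 0.0878 to 0.213, within 5.34e-39 to 0.213 over 14 alternatives.

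In bipolar cells no gene passed by edgeR in rd10 (0 of 18176, 246 at unadjusted p below 0.05, 9 by DESeq2) or in P347S (0 of 18176, 1860 at unadjusted p below 0.05, 183 by DESeq2). The interferon list lay above 0 in 26 of 26 in rd10 (median 1.05, 11 adjusted over the list alone, adjusted p = 4.26e-51) and passed with an estimated correlation (adjusted p = 0.0288). Stat1, which carries the interferon signal, stood at 1.13 ± 0.15 (adjusted p = 0.388). In P347S the list lay above 0 in 23 of 26 (0.55, adjusted p = 3.87e-07, and adjusted p = 0.326 with an estimated correlation). Müller reactivity genes were above 0 in 25 and 26 of 29 (medians 0.47 and 0.49, adjusted p = 5.55e-23 and 1.41e-09), and nuclear oxidative phosphorylation genes below 0 in 44 of 46 in rd10 (-0.20, adjusted p = 3.61e-07). These had adjusted p = 0.145, 0.46 and 0.669 with an estimated correlation. In all, 6 lists passed upward and 10 downward in rd10, and 6 and 7 in P347S, crystallins upward in both. Without P347S P10 replicates 1 and 2 the count in P347S became 4 and 3.

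In microglia, a class that may include macrophages, no gene passed in rd10 by edgeR (0 of 12589, 256 at unadjusted p below 0.05, 2 by DESeq2). Disease-associated genes still lay above 0 in 26 of 27 (median 0.47, 5 adjusted over the list alone, adjusted p = 9.55e-18, and adjusted p = 0.0904 with an estimated correlation). Fabp5 stood at 2.77 ± 0.50, Spp1 at 2.68 ± 0.56, Gpnmb at 2.12 ± 0.45 and Cst7 at 1.72 ± 0.35. Immediate early genes lay below 0 in 23 of 23 (-0.42, adjusted p = 5.56e-06) and rod synapse genes in 18 of 22 (-0.24, adjusted p = 0.0356), and interferon genes above it in 24 of 26 (0.54, adjusted p = 2.29e-12), among 3 lists that passed upward and 5 downward. In P347S, Cacna1a, a neuronal calcium channel, rose from 16.4 to 235 CPM (3.87 ± 0.40, adjusted p = 0.0362) and Slc1a3, a glial glutamate transporter, from 24.0 to 297 (3.55 ± 0.32, adjusted p = 0.0261). Heat shock genes were below 0 in 18 of 19 (-0.65, adjusted p = 1.63e-07) and antioxidant genes in 19 of 22 (-0.43, adjusted p = 0.000212), among 8 lists that passed downward and 0 upward, so the shift was broad and not particular to them. All 26 rod phototransduction genes lay below 0 as well (-0.98, adjusted p = 1.49e-06). No list passed with an estimated correlation (adjusted p = 0.615 for the smallest). With the replicate number as a block, 62 genes passed in P347S in place of 2, and 0 in rd10. Both calls were lost without WT P30 replicate 1 (adjusted p = 0.257) or 2 (0.109 and 0.0625), and Cacna1a (0.0526) without P347S P10 replicate 1, within 3.19e-20 to 0.257 over 14 alternatives. Without WT P60 replicates 1 and 2 the count was 4 and 3.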

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

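The tests of free RNA, of a local variant and of mixed samples were chosen after the result was seen, and the depth test of the WT rods and the exchanges of labels before. The first test of free RNA for the genes around Trhde, their ratio to Rho over that in rods, gave a median of 2.83 (0 to 72.9 over 24 ratios), decided nothing, and was replaced after its result was seen.

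The difference between the models themselves passed the edgeR test for 3 genes at each age, which marks them for a closer look. At P10 the log2 difference of P347S from rd10 rods was 6.06 ± 0.48 for Trhde (adjusted p = 0.00132), 7.05 ± 0.72 for 4930473D10Rik (0.0062) and 8.04 ± 0.76 for Gm31182 (0.00406). At P30 it was 3.66 ± 0.44 for Trhde, 5.94 ± 0.74 for Gm31182 and 3.66 ± 0.45 for Dock8 (all adjusted p = 0.0391). In rd10 rods 4930473D10Rik held 2 UMIs at P10 and Gm31182 held 2 at P10 and 3 at P30, so their fitted changes depend on the prior count. By raw UMIs 4930473D10Rik was 140-fold higher at P10 (counting interval 38.6 to 1160), and Gm31182 306-fold at P10 (84.6 to 2530) and 60.9-fold at P30 (20.5 to 298). Dock8 stood at 16.1 and 21.8 CPM in P347S rods at P10, 60.8 at P30 and 83.4 at P60, against 4.82 to 11.3 in the 9 libraries of the other genotypes.

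Trhde, 4930473D10Rik and Gm31182 span 486.3 kb of chromosome 10 (114398823 to 114885131). This place was seen before the test was written, and 2 of the genes overlap, so the span describes the pattern and does not test its cause. RNA from other cells as the whole cause is argued against, since the median rise in Müller glia, bipolar cells and microglia was 0.051 of that in rods (-0.012 to 0.816 over 18 ratios), although in cones it was 1.51 to 6.54 times that in rods. A variant or insertion near Trhde carried by the P347S line may underlie the rise, but no sequence was examined and antisense overlap leaves the strand open. Of 13 tested genes within 1 Mb, 4 passed over the ages and the other 9 had adjusted p of at least 0.237. An effect of the altered rhodopsin on this region stays open and was not tested, because line and genotype coincide.

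In WT P60 replicate 1, 67 rods (106982 UMIs) lay in the cluster that held most mutant rods, with Dpp10 at 1140 CPM (947 to 1362) against 61.3 in its other rods, though this cluster was selected for such genes. Cells of a P347S library are argued against, since Trhde, 4930473D10Rik and Gm31182 together held 0 UMIs, an upper limit of 34.48 CPM against 521.03 in P347S P60 rods of that cluster. Cells of the rd10 P30 library are argued against by Xist, at an upper limit of 34.48 CPM against 513.45. Depth is argued against by a median UMI count 0.832 times that of the other rods. A state of single WT rods that resembles mutant rods may exist, as a hypothesis, and no biological explanation was tested.

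Fgf2 and Dpp10 were higher outside rods as well. The ratio of Fgf2 to Rho in cones was 1.81 times that in rods (1.17, 1.81 and 2.50 in the 3 mutant libraries at P30 and P60), so rod RNA may account for the rise of Fgf2 in cones. For Dpp10 in Müller glia the ratio was 0.35 (0.10, 0.349 and 0.420). This met neither bound that was set, within a factor of 2 or above 4 in each library. It lay below that in rods in each library, so rod RNA could account for the whole rise, and own expression cannot be told apart from it. The ratio was not taken for Dpp10 in cones. Expression by cones or glia themselves stays open in both cases.

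Exchanging genotype labels within age gave 27 splits for P347S, the real one included. Chance cannot be excluded for rods (260 calls, 2 splits as large, highest other 315), cones (52, 2 splits, 243) or Müller glia (4, 3 splits, 90). The highest other in all 3 classes exchanged WT at P10 with P347S P10 replicate 2 and kept the real labels at P30 and P60. In cones and Müller glia it gave several times the real calls, which points to a structure of the samples. In rods the other split at P10 alone gave 30 calls, and the 24 splits that exchanged a label at P30 or P60 gave 0. In bipolar cells (0 calls, 27 splits, 9) the real count of 0 makes every split as large, so the exchange says nothing. In microglia chance cannot be excluded without the block (2 calls, 3 splits, 32), and a split with several times the real calls points to a structure there too. Same-numbered libraries deviated together in this class, though the labels give no pairing. With the number as a block 62 genes passed. The highest was 21 in the other splits that keep both numbers in each group of 2 libraries. Those 8 splits are too few for a share under 0.05, and of the 19 splits that put the same number in a group of 2 libraries 1 could not be fitted and the highest gave 80. This exchange with the block was chosen after the results were seen. For rd10 the 12 splits are too few for a share under 0.05, with 2 calls against a highest other of 0 in cones (1 split as large) and 7 against 0 in Müller glia (1 split). The count of 0 says nothing in rods (highest other 2), bipolar cells (0) and microglia (0), with 12 splits as large in each.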

How the results depend on the processing

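The test without the rod clusters of low Malat1 was chosen after the results were seen. Below, counts of genes past the threshold are given for rods as rd10 at P10, P18, P30 and over the ages, P347S at P10, P30, P60 and over the ages, P347S against rd10 at P10 and P30, WT at P60 against P10, and genes common to both models at P30, then for cones, Müller glia, bipolar cells and microglia in rd10 and P347S. Counts not named stayed within 1.5 times of those in the report, and the cause of the moves was not tested unless stated.

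By DESeq2, 17 of 20 counts moved and 18 of 20 were higher. In rods rd10 counts were 8 at P18, 247 at P30 and 44 over the ages, P347S counts 43, 112, 594 and 602, the 2 comparisons between models 39 and 15, and common genes 68. Elsewhere the counts were 4 for rd10 cones, 42 and 99 in Müller glia, 9 and 183 in bipolar cells and 2 and 10 in microglia. Of the 260 P347S calls over the ages in rods, 249 were shared. Without the filter on low counts more genes were tested and all 20 counts rose. In rods they were 5, 33, 752 and 101 in rd10, 190, 248, 1125 and 1317 in P347S, 153 and 48 between models, 2013 in WT and 153 common genes. Outside rods they were 26 and 360 in cones, 209 and 844 in Müller glia, 3 and 70 in bipolar cells and 23 and 168 in microglia. RLE scaling moved 3 of 21 counts, to 314 for P347S rods at P60, 6 for P347S against rd10 at P30 and 1 for P347S Müller glia. An additive model of age and genotype gave 49 for P347S rods, 0 for rd10 cones, 24 and 9 in Müller glia, 13 in P347S bipolar cells and 9 in P347S microglia.

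With at least 1000 genes per cell, 5 counts moved, to 323 for P347S rods at P60, 8 for rd10 rods and 505 for P347S rods over the ages, 5 for P347S against rd10 at P30 and 1 for rd10 cones, and the rd10 difference in the share of rods reversed to -7.52 points (exact permutation p = 0.667), while that in P347S became -11.95 (p = 0.444). In this setting amacrine cells differed by 12.92 points in P347S, bipolar cells by 8.51 in rd10 and 7.39 in P347S, pigment epithelium by -0.37 in place of -0.61 in rd10, and microglia in P347S by 0.06 in place of -0.27. With doublets kept, P347S against rd10 at P30 and rd10 cones fell to 0, and Müller glia to 4 in rd10 and 0 in P347S. With equal cells per library, which leaves fewer UMIs, 14 counts moved. In rods they were 15 for rd10 at P30, 1, 21 and 68 for P347S at P10, at P30 and over the ages, 1 and 1 between models, 330 in WT and 10 common genes. Elsewhere they were 0 and 24 in cones, 0 and 0 in Müller glia, 1 in P347S bipolar cells and 0 in P347S microglia. Without the rod clusters of low Malat1, 7 of 12 counts moved, to 123 for rd10 at P30, 8 for rd10 over the ages, 718 and 822 for P347S at P60 and over the ages, 5 between models at P30, 1604 in WT and 50 common genes. Of the 208 list tests in the 8 rod comparisons with WT, 86 passed, 31 up and 55 down, against 0 with an estimated correlation.

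Outside microglia at least 1 pair of groups per class stayed below the 0.1 used to judge pairing. Other pairs in cones, Müller glia and bipolar cells were as high as those in microglia, so pairing there was neither shown nor excluded. The block with the replicate number gave 5, 36, 510 and 96 in rd10 rods and 174, 235, 1025 and 1486 in P347S rods. In the same class it gave 153 and 45 between models, 1861 in WT and 135 common genes. It gave 14 and 263 in cones, 13 and 24 in Müller glia, 1 and 71 in bipolar cells and 62 in P347S microglia, and left rd10 microglia at 0. The correlations of same-numbered libraries were 0.11, 0.077 and 0.126 in rods, 0.013, 0.352 and 0.103 in cones, 0.032, 0.268 and 0.283 in Müller glia and 0.007, 0.398 and 0.21 in bipolar cells.

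Leaving out each of 6 libraries in turn, which leaves fewer samples, gave in rods 0 to 4, 0 to 8, 38 to 646 and 0 to 41 calls in rd10 and 2 to 34, 35 to 135, 29 to 1111 and 95 to 1523 in P347S. Between models it gave 3 to 32 and 0 to 16, in WT 725 to 1552 and for common genes 13 to 98. It gave 0 to 11 and 13 to 166 in cones, 0 to 8 and 0 to 1 in Müller glia, 0 to 4 in P347S bipolar cells, 0 to 4 in P347S microglia, and 78 to 107 for rod lists. WT P60 replicate 1 held 525 rods with 906426 UMIs, the fewest of any library in that class. Small changes were called seldom: in simulated counts for rd10 rods at P30 (18790 genes), 10% of 2-fold changes were called, and whether depth or the number of libraries limits this was not tested. Of 79 named gene calls, none reversed. Equal cells lost 30, P347S P10 replicate 2 left out lost 24, WT P30 replicates 1 and 2 left out 17 and 16, P347S P10 replicate 1 left out 16, doublets kept 15, WT P60 replicates 1 and 2 left out 2 and 3, at least 1000 genes 3, DESeq2 2, RLE 1, and the block and no filter 0, while the additive model lost 16 of 33. The mean differences in the share of rods were 1.74, 0.75 and 1.8 points in rd10 and -18.27, -18.05 and -18.16 in P347S with the other clusterings and doublets kept.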

Other observations

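The test of clustered genes over all classes was written before its result, and the genes singled out here were chosen after their values were seen. In rods of rd10 at P30, Cst7, a cysteine protease inhibitor of activated microglia, held 66 UMIs against 6 in WT, a ratio of 51.5 (22.4 to 145), and passed the edgeR test (5.35 ± 0.97, adjusted p = 0.0494). Cryge rose by 5.68 ± 0.59 (adjusted p = 0.0115), from 0.602 and 0.821 to 38.5 CPM. An erythroid cluster led also by the lens genes Crygc, Crygb and Crygd took 4.25% of the cells of that library and 9.69% of P347S at P60, against 0.15 to 2.44% of the others.

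In P347S microglia Slc1a3 stood at 126 and 203 CPM at P10, 344 at P30 and 382 at P60, against 10.0 to 45.5 in the 9 other libraries. Cacna1a stood at 342, 176, 206 and 240 CPM in the P347S libraries against 7.50 to 43.4. Rtkn2 in rods stood at 64.7 and 56.3 CPM in P347S at P10, 46.0 at P30 and 42.8 at P60, against 1.68 to 14.4 in the other libraries.

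Cluster 4 without a name, with amacrine and ganglion markers alike, held 58.7% of the cells of P347S at P30, which made up 93.2% of it, and was led by Vip, Cartpt, Nefl and the muscle genes Myl1 and Mylpf. Cluster 7, with Müller and rod markers alike, held 48.3% of WT P30 replicate 1, which made up 91.8% of it. Clusters mostly of 1 library can be that library and not a cell type.

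At P10, AA465934 (chromosome 11, 83291699 to 83294632), Cmss1 (chromosome 16, 57302000 to 57606864) and AY036118 (chromosome 17, 39847113 to 39848035) were higher than in WT and rd10 in both P347S libraries in all 5 classes, out of 7079 genes eligible. A variant shared by the line was tested by their nearness, with 0 of the 3 within 5 Mb of another, and the set is too small to decide. AY036118 was also a leading gene of cluster 4 and Cmss1 of cluster 7, the unnamed clusters mostly of 1 library each. A difference between libraries unrelated to the line was not tested. In rods the mean CPM in P347S, WT and rd10 was 51.0, 8.8 and 9.1 for AA465934, 1428, 350 and 271 for Cmss1 and 810, 167 and 137 for AY036118.

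Xist in rods was 0 CPM in WT P60 replicate 1 and 0.189 in WT at P18, against 125 to 1224 in the other 11 libraries. Ddx3y was 0.047 CPM in rd10 at P10 and 0.957 in P347S P10 replicate 2, against 7.34 to 78.4 in the others. The labels do not give the sex of these mice, and most libraries held both transcripts. The rd10 comparison at P18 thus set a WT library nearly without Xist against one that held it. At P10 an rd10 library nearly without Ddx3y was set against a WT library that held it. A difference by sex cannot be told from one by genotype in these comparisons. Sex can also add to the spread between the libraries of WT at P60 and of P347S at P10.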
